A study of Homo sapiens with 6 samples.

How the data were processed

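Gene expression was measured by RNA sequencing in K562 cells, an established human erythroleukemia line that grows in suspension and carries markers of erythroid and megakaryocytic precursors. There were 6 libraries, 3 labelled wild type and 3 labelled ARID4B knockout. Per the labels' protocols, total RNA was purified on columns and treated with DNase I, and messenger RNA libraries were made with a strand-preserving kit that incorporates dUTP into the second strand, then sequenced as paired ends on an Illumina instrument. The labels name no batch, day or clone. They do not say whether the replicates of a genotype came from separate cultures or separate edited clones. The p-values therefore measure only the spread between these libraries, which in wild type may be technical. The way the knockout was made is not given in the sources used here.

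The main table held estimated counts per gene and library, deposited by the authors without normalization. The submitters' processing notes name STAR 2.4 and RSEM 1.2.14 and the human genome builds hg19 and GRCh37, without a role or an order. RSEM shares reads that fit several genes between them, and between 6.9% and 11.7% of the values of a library were not whole numbers. Near-identical copies such as HBG1 and HBG2, HBA1 and HBA2, or members of the histone clusters are therefore uncertain as single genes, although their sum is less so. Whether the counting used the strand is not given in the sources used here, so reads of overlapping and antisense genes may have been assigned to either. The table had 34495 rows. A spreadsheet had turned 27 gene symbols into dates, and all 27 were restored from the description in their own row. Start positions in the table count from 0, since end minus start equalled the RefSeq gene length in 3059 rows with a single transcript and was 1 below it in 259, so 1 was added to every start and all coordinates are on hg19. A second table held the authors' own comparison of knockout with wild type for 3153 genes, with log2 fold changes and p-values deposited by the authors, unadjusted and adjusted. All of its genes had an unadjusted p up to 0.05, and the smallest absolute log2 fold change in it was 0.59. The test behind it is not given in the sources used here.

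Library totals ran from 21701404 to 30346244 estimated counts. The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test on genotype, with TMM scaling and the default expression filter (minimum count 10), which left 13696 genes. P-values were adjusted with the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were counted as past the threshold. Levels are CPM, that is counts scaled to a common library total after TMM scaling, given as mean ± SD with n = 3 per genotype, and fold changes are log2 of knockout over wild type with their standard error (SE). For a gene with 0 counts in all libraries of a genotype, the fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts the ratio of summed counts is given with an exact (Clopper-Pearson) 95% interval. Bounds and intervals cover counting error only.

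Before the data were examined, 32 gene lists were written to fit an erythroleukemia line, the KIT and Src pathway named in the study's title, the SIN3-HDAC complex to which ARID4B belongs, other cell types, growth and stress. Main lists were ARID4B and the SIN3-HDAC complex, KIT signalling, Src family kinases, globins, erythroid differentiation, erythroid and megakaryocyte transcription factors, and megakaryocyte and platelet genes. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members of a list move one way on balance. All 31 lists so tested are reported. Members that did not pass the expression filter were left out. A member silent in wild type passes it only through the knockout, which favours rises in counts and medians. The list of mitochondrially encoded genes had no member under its symbols in the table and was not tested. Genes were named by a rule also fixed beforehand: ARID4B, KIT, SRC, LYN, CSK, GATA1, GATA2, KLF1, HBG1, HBG2, HBZ, HBE1, ITGA2B, CD34 and 1 further gene always where tested, then the 8 largest rises and the 8 largest falls among genes past the threshold with at least 5 CPM in the higher group, no overlap between genotypes and a gene symbol, then up to 2 members each way of every main list and up to 1 each way of every other list among members past the threshold with at least 1 CPM in the higher group. The rule gave 74 genes, of which 2 are not reported here.

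The calculation was tested on simulated counts with the means and totals of these libraries and 50 genes changed at each of 4 sizes, among 13540 genes that passed the filter in the simulation. It recovered 98% of genes changed 8-fold, 82% at 4-fold, 66% at 2-fold and 16% at 1.5-fold, and called 10 unchanged genes. With the spread of each genotype simulated separately, among 13552 genes, the shares were 96%, 68%, 54% and 20%. These shares depend on how many genes are changed and do not carry over to data with many more calls. With no gene changed, 3 of 13570 genes were called, and 897 had an unadjusted p under 0.05.

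Alternatives fixed beforehand were 3 other scalings (RLE size factors, library totals alone, upper quartile factors), no expression filter or a filter of at least 1 CPM in 3 libraries, unrounded counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library. An offset for the level of neighbouring genes and a fit with a spread of its own for each genotype were added after seeing the data. For chromosomal neighbourhoods, genes with a mean of at least 5 CPM were ordered along hg19 and split into 238 blocks of 40 neighbouring genes (the last block of a chromosome takes the remainder), and the median log2 level per library was taken relative to the wild-type mean. Pairs of wild-type libraries differed by more than sampling noise (chi-square per degree of freedom 3.05 to 8.12). Repeat libraries of the same RNA can also differ so, and this cannot show that the libraries are separate samples. All 6 libraries were counted as separate because the labels number them separately. Tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.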

Results

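Messenger RNA was sequenced from K562 erythroleukemia cells, 3 wild-type and 3 ARID4B knockout libraries, in a study whose title sets ARID4B beside the KIT-Src pathway and the differentiation of haematopoietic progenitors. ARID4B encodes a DNA-binding subunit of the SIN3-HDAC corepressor complex, which removes acetyl groups from histones. Library totals were 27889850, 30346244 and 23959811 estimated counts for wild-type replicates 1 to 3 and 24287385, 21701404 and 23199532 for knockout replicates 1 to 3. More genes had counts above 0 in the knockout libraries (19188, 19066 and 18299) than in the wild-type libraries (16744, 16835 and 16593). Rows of the mitochondrial chromosome took 1.12%, 0.83% and 0.98% of the counts in wild-type and 1.08%, 1.64% and 1.67% in knockout replicates 1 to 3. The first principal component of log2 levels held 68.5% of the variance. Knockout libraries varied far more among themselves than wild-type libraries, with a biological coefficient of variation of 32.3% against 4.8%.

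ARID4B (chromosome 1, 235294498 to 235491532 on hg19) was measured first, since it checks the labels. Its level was 40.1 ± 1.45 CPM (SD, n = 3) in wild type and 7.81 ± 0.656 CPM (n = 3) in the knockout. The log2 fold change was -2.36 (SE 0.10, edgeR quasi-likelihood adjusted p = 0.000132), which is 5.13-fold lower, and all knockout libraries, at 8.52, 7.22 and 7.68 CPM, lay below all wild-type libraries. Neighbouring genes in its chromosomal block also stood lower, with block medians of -0.35, -0.66 and -0.26 (log2) in knockout replicates 1 to 3. With those medians removed, a calculation chosen after seeing the data, the log2 fold change of ARID4B was -1.94. Total gene counts do not show which part of a transcript remained.

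**Figure D1:**
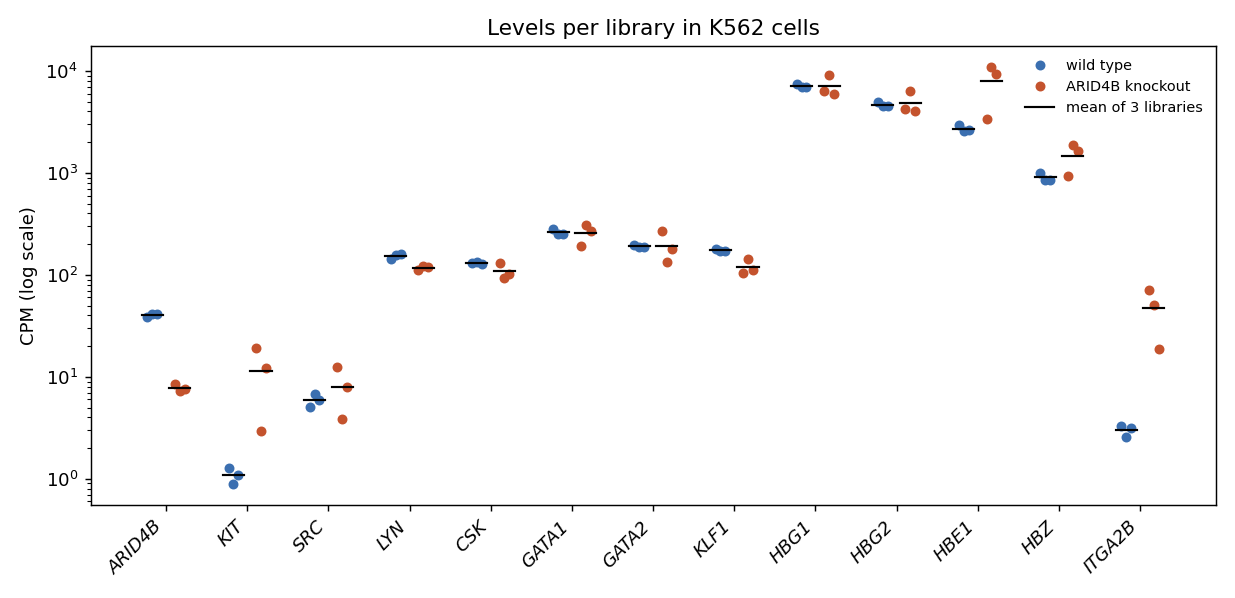
Levels of ARID4B and 12 other genes named beforehand, in CPM on a log scale, with a point for each of the 3 wild-type and 3 ARID4B knockout libraries and a line at the mean of each genotype. ARID4B lies at 40.1 CPM in wild type and 7.81 CPM in the knockout, while KIT and ITGA2B lie higher in all knockout libraries and the points of GATA1, GATA2 and HBG1 overlap.

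Loss of ARID4B went with a transcriptome in which large changes were mostly rises. Of 13696 genes tested, 4619 passed the threshold, 2512 higher and 2107 lower in the knockout. Among the 1710 that also differed at least 2-fold, 1563 were higher and 147 lower. Counts of gene list members past the threshold are to be read against 4619 of 13696. The SIN3-HDAC, KIT, Src and erythroid differentiation lists lay near that overall rate. Every knockout library lay above every wild-type library for 3642 genes and below for 3518, together 52.3% of the tested genes. Chance gives 10% only where both genotypes spread alike, which they did not, so that share is too low a baseline here. Of tested genes, 75 were under 0.2 CPM in every wild-type library and at 1 CPM or more in every knockout library, and the reverse held for 1 gene. The balance of small rises and falls depended on the scaling. With library totals alone, which moved the median of all genes by 0.11 (log2), 3120 genes rose and 1283 fell (70.9% rises against 54.4%), and with upper quartile factors 2947 rose and 1451 fell. An offset for neighbouring genes, added after seeing the data, gave 3000 rises and 1673 falls. Fewer genes passed when a wild-type library was left out, namely 2349, 2097 and 2178 without wild-type replicate 1, 2 or 3. Of these, 1011, 940 and 1003 differed at least 2-fold. The test fits 1 spread per gene for both genotypes, so the wider knockout spread then weighs more. Without knockout replicate 1, 2 or 3, 5456, 4853 and 5437 genes passed.

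**Figure D2:**
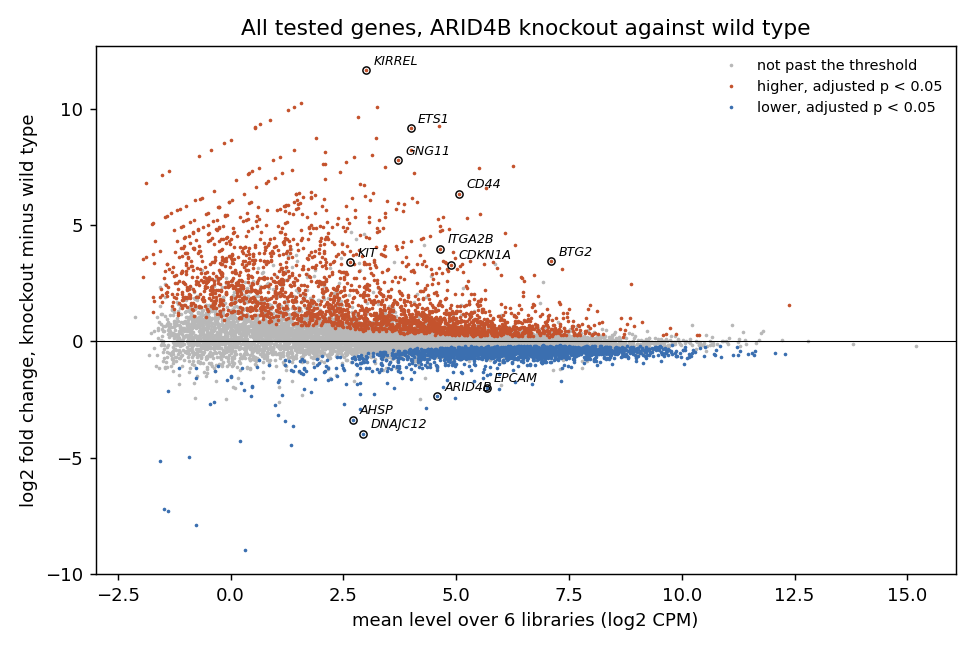
Log2 fold change of knockout over wild type against mean level over the 6 libraries (log2 CPM), with a point for each of 13696 tested genes, coloured where the adjusted p was under 0.05. Of genes past the threshold and changed at least 2-fold, 1563 lie above 0 and 147 below, and circled genes are named.

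The genes with the largest rises were almost silent in wild type. ETS1, a transcription factor of haematopoietic and endothelial cells, went from 0.054 to 31.8 ± 1.21 CPM (n = 3) with a log2 fold change of 9.16 (SE 0.38, adjusted p = 0.000113). KIRREL, an adhesion molecule of the kidney slit diaphragm family, had no count in wild type and 16.1 ± 8.93 CPM in the knockout, at least 419-fold higher against a floor of 3 counts over the group. FLI1, an ETS factor of the megakaryocyte lineage, and the protease inhibitor A2M had no wild-type count either, and were at least 161-fold and at least 143-fold higher. FLI1 spread from 0.50 to 11.9 CPM among knockout libraries. GBP5, an interferon-inducible GTPase, rose to 48.8 ± 42.2 CPM (log2 fold change 9.24, SE 1.29, adjusted p = 0.00355). Counts near 0 in wild type left wide intervals for 2 others: the ratio of summed counts was 1170 (95% interval 210 to 46300) for the coagulation inhibitor TFPI2 and 608 (109 to 24100) for the connexin GJA4. KIRREL lies in a block of chromosome 1 whose median was 0.60 higher in knockout replicate 2. With limma-voom the calls of FLI1, GBP5 and GJA4 were lost (adjusted p = 0.0526, 0.158 and 0.0539). Leaving out any wild-type library ended the call of FLI1 (adjusted p 0.056 to 0.0597), and leaving out wild-type replicate 2 that of GJA4 (0.0501).

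ARID4B itself was among the 8 largest falls. DNAJC12, a co-chaperone, fell from 14.4 ± 0.298 to 0.904 ± 0.274 CPM (log2 fold change -3.98, SE 0.26, adjusted p = 0.000475). AHSP, the chaperone of free alpha globin, fell from 11.9 ± 1.58 to 1.15 ± 1.37 CPM (log2 fold change -3.37, SE 0.78, adjusted p = 0.0172). GLIPR2, ARHGAP22, the muscle intermediate filament gene DES, the lymphoid receptor TNFRSF8 and the lipoprotein lipase LPL fell with log2 fold changes of -2.90, -2.86, -2.69, -2.42 and -2.26. Leaving out any wild-type library ended the calls of AHSP (adjusted p 0.059 to 0.0684), ARHGAP22 (0.0503 to 0.0539), DES (0.05 to 0.0506), LPL (0.0547 to 0.0581) and TNFRSF8 (0.109 to 0.112). TNFRSF8 also missed the threshold without knockout replicate 2 or 3 (0.0641 and 0.0798), with library totals alone (0.0546), with upper quartile factors (0.0514) and with the neighbourhood offset (0.0897). Over all named genes, 66 passed the threshold, and 24 of these failed it when at least 1 of the wild-type libraries was left out.

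Most subunits of the SIN3-HDAC complex did not pass the test. Of 23 measured members including ARID4B, 1 rose and 6 fell, the same numbers when adjusted over the list alone, and 16 did not pass. Over all tested genes 4619 of 13696 passed, a similar share. HDAC1, a catalytic deacetylase, went from 308 ± 1.86 to 215 ± 28.4 CPM (log2 fold change -0.52, adjusted p = 0.00853), in a block of chromosome 1 with medians of -0.46, -0.41 and -0.20. ARID4A, the paralogue of ARID4B, rose from 14.8 ± 1.22 to 20.9 ± 3.24 CPM (0.50, adjusted p = 0.0366), but missed the threshold when any wild-type library (adjusted p 0.0854 to 0.135) or knockout replicate 2 (0.0576) was left out and with no expression filter (0.0597). As a whole the list did not pass with camera (adjusted p = 0.134), except without wild-type replicate 1 (0.041), but passed with fry, downward (0.00766). These tests include ARID4B, whose fall comes from the knockout itself, and the list was not tested without it. The median of the list was -0.12. With library totals alone it was -0.01, and 3 members rose and 3 fell. Without wild-type replicate 1, 2 or 3, 0 rose and 4, 3 and 3 fell, while without knockout replicate 3 there were 3 rises and 5 falls.

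KIT, the receptor of stem cell factor (chromosome 4), was low in wild type at 1.08 ± 0.194 CPM and reached 19.2, 2.94 and 12.3 CPM in the knockout libraries, a mean of 11.5 ± 8.13 (n = 3). Its log2 fold change was 3.40 (SE 0.66, adjusted p = 0.00959). This call was lost without wild-type replicate 2 or 3 (adjusted p = 0.053 and 0.0507) and with limma-voom (0.0628). Of 27 tested members of KIT signalling, 5 rose and 3 fell (7 and 3 adjusted over the list alone) and 19 did not pass. PLCG2, a phospholipase, rose from 3.20 to 12.7 CPM (1.99, adjusted p = 0.0204). It missed the threshold when any wild-type library was left out (0.0533 to 0.088). The adaptor GRB10 and the transcription factor STAT5A fell by 0.66 and 0.83 on the log2 scale (adjusted p = 0.00259 and 0.0101). The list did not pass (camera adjusted p = 0.707, median 0.17). The number of its members that rose was 8 with library totals alone or without knockout replicate 2, and 3, 2 and 2 without wild-type replicate 1, 2 or 3. Its median was 0.01 without knockout replicate 1 and 0.35 without knockout replicate 2.

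Among Src family kinases, SRC itself measured 5.93 ± 0.885 CPM in wild type and 8.04 ± 4.28 CPM in the knockout, with overlapping libraries and an adjusted p of 0.435 (log2 fold change 0.44, SE 0.40). LYN, expressed in wild type at a higher level than SRC or FYN, fell from 154 ± 8.23 to 117 ± 4.63 CPM (-0.40, SE 0.07, adjusted p = 0.00697). FYN rose from 22.3 ± 0.26 to 77.5 ± 22 CPM (1.80, SE 0.20, adjusted p = 0.00199). CSK, the kinase that phosphorylates the inhibitory tail of the family, measured 131 ± 2.37 and 108 ± 18.9 CPM (-0.27, adjusted p = 0.133), and passed only without knockout replicate 1 (-0.42, adjusted p = 0.00507). CAV1, a membrane scaffold, rose from 0.331 to 2.65 ± 1.92 CPM (adjusted p = 0.03), but knockout replicate 1 lay within the wild-type range and the call was lost with limma-voom (0.155) and when any wild-type library (0.0887 to 0.116) or knockout replicate 2 or 3 (0.068 and 0.0645) was left out. In all, 5 of 18 tested members rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone. When any wild-type library was left out 2 rose, with library totals alone 8 rose, and without knockout replicate 1 there were 3 falls. Camera gave an adjusted p of 0.462 and fry 0.00874.

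Downstream of these kinases, ERK feedback and immediate early genes rose in 12 of 21 tested members (14 adjusted over the list alone) and fell in 0. PHLDA1, a gene induced by growth factors, rose from 1.41 to 24.0 ± 11.8 CPM (4.08, SE 0.41, adjusted p = 0.00148). The list passed (camera adjusted p = 1.4e-05, median 1.11, with 0.72 and 1 fall without knockout replicate 1), but not with an estimated correlation (adjusted p = 0.314). STAT5 targets rose in 4 of 12 members (5 adjusted over the list alone), SOCS1 among them at 2.11-fold (adjusted p = 0.0198), and camera gave 0.171 for the list while fry gave 0.0203. When any wild-type library was left out 2 of these targets rose and SOCS1 missed the threshold (0.0666 to 0.0941).

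The list with the highest median was that of megakaryocyte and platelet genes, of which 16 of 22 tested members rose (17 adjusted over the list alone) and 0 fell, with a median log2 fold change of 2.14. The list held 35 genes before the expression filter. Without knockout replicate 2 or 3 there was 1 fall. ITGA2B, the platelet integrin alpha IIb (chromosome 17), went from 3.01 ± 0.393 to 47.1 ± 26.6 CPM, with knockout libraries at 71.7, 50.8 and 18.9 CPM (3.97, SE 0.50, adjusted p = 0.00272). GNG11, a G protein subunit of platelets, rose from 0.115 to 26.1 ± 9.04 CPM (7.78, SE 0.41, adjusted p = 0.000254). MMRN1, a protein of platelet alpha granules, had 1 count in wild type and a ratio of summed counts of 333 (95% interval 59.4 to 13200). Camera gave the list an adjusted p of 2.17e-06, which became an adjusted p of 0.392 with an estimated correlation. Members near 0 in wild type, such as GNG11 and MMRN1, passed the expression filter only through the knockout libraries and could only rise. The counts, the median and the test include them.

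Erythroid genes moved in both directions. Of 37 tested members of the erythroid differentiation list, 9 rose, 5 fell and 23 did not pass, also when adjusted over the list alone, and camera gave an adjusted p of 0.796. Besides AHSP, the embryonic myosin light chain MYL4 fell from 128 ± 6.37 to 62.9 ± 26 CPM (adjusted p = 0.0408). That call was lost with library totals alone (0.0545), with upper quartile factors (0.0535) and when any wild-type library was left out (0.101 to 0.12). TRIM10 and TSPAN33, both found in maturing red cells, rose from under 1 CPM to 2.44 ± 1.11 and 7.96 ± 4.29 CPM (log2 fold changes 4.51 and 4.16, adjusted p = 0.00306 and 0.00482). The median of the list was -0.05 while its mean was 0.38 and camera pointed up, and library totals alone turned the median to 0.06. When any wild-type library was left out 7 members rose and 1 fell. The median was 0.21 (13 rises, 7 falls) without knockout replicate 1 and -0.22 (7 and 4) without knockout replicate 2.

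Of the globins, the embryonic HBE1 rose from 2711 ± 208 to 7874 ± 3990 CPM (2.90-fold, log2 fold change 1.54, SE 0.39, adjusted p = 0.0242), with knockout replicate 1 at 3376 CPM and replicates 2 and 3 at 10972 and 9274. HBA2 rose 1.49-fold (adjusted p = 0.0384). Both missed the threshold when any wild-type library was left out (adjusted p 0.0842 to 0.0937 for HBE1 and 0.0894 to 0.143 for HBA2), and without knockout replicate 2 or 3 (0.0574 and 0.0542 for HBE1, 0.0934 and 0.0923 for HBA2). HBA2 also did so with limma-voom (0.0513) and no expression filter (0.0511). HBZ measured 901 ± 83.8 and 1479 ± 492 CPM (0.71, adjusted p = 0.0597), and passed with library totals alone (0.0359), with upper quartile factors (0.0431), with DESeq2 (0.0099), without knockout replicate 1 (0.00146), and in both fits added after seeing the data, the neighbourhood offset (0.0265) and a spread of its own for each genotype (0.0328). The fetal genes HBG1 and HBG2, which share reads, differed by less than the spread between replicates at 7121 ± 238 against 7092 ± 1680 CPM and 4674 ± 244 against 4881 ± 1310 CPM (adjusted p = 0.981 and 0.81), except that HBG1 passed without knockout replicate 2 (-0.22, adjusted p = 0.0257). In total 2 of 9 tested globins rose and 0 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.789). When any wild-type library was left out 0 rose. Leaving out knockout replicate 1, 2 or 3 gave 4, 0 and 0 rises and 0, 2 and 0 falls.

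GATA1 and GATA2, transcription factors of blood precursors, differed by less than the spread between replicates. GATA1 measured 263 ± 18.7 and 258 ± 59.3 CPM (-0.02, SE 0.17, adjusted p = 0.922), in a block of chromosome X with medians of -0.62, -0.02 and 0.05, and GATA2 191 ± 2.96 and 194 ± 67.4 CPM (0.02, SE 0.23, adjusted p = 0.953). KLF1, an activator of adult globin, fell from 174 ± 5.83 to 120 ± 20.2 CPM (-0.54, SE 0.12, adjusted p = 0.0152). Its call was lost when any wild-type library was left out (0.056 to 0.0654). Of 27 tested erythroid and megakaryocyte factors, 5 rose and 7 fell (6 and 7 adjusted over the list alone). ID2, an inhibitor of helix-loop-helix factors, rose 5.54-fold next to FLI1, while IKZF1 fell by 1.03 and NFIA by 1.78 on the log2 scale (adjusted p = 0.0021, 0.000923 and 0.00617). NFIA lies in a block with medians of -0.57, -0.55 and -0.18. The list did not pass (camera adjusted p = 0.462, down, although its mean was 0.30), and its median was -0.06 also with FLI1 at its bound (-0.17 without knockout replicate 2). Of the factors 4, 2 and 3 rose and 2, 2 and 3 fell without wild-type replicate 1, 2 or 3. Heme synthesis and iron genes fell in 3 of 22 members (3 adjusted over the list alone) and rose in 0 (camera adjusted p = 0.373). Of these the mitochondrial transporter ABCB10 fell 2.01-fold (adjusted p = 0.0228), in the same distal block of chromosome 1 as ARID4B. Its call was lost with the neighbourhood offset (-0.58, adjusted p = 0.127) and when any wild-type library was left out (0.072 to 0.0798), where 1 member of the heme list fell. That list had 2 rises and 4 falls without knockout replicate 1.

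**Figure D3:**
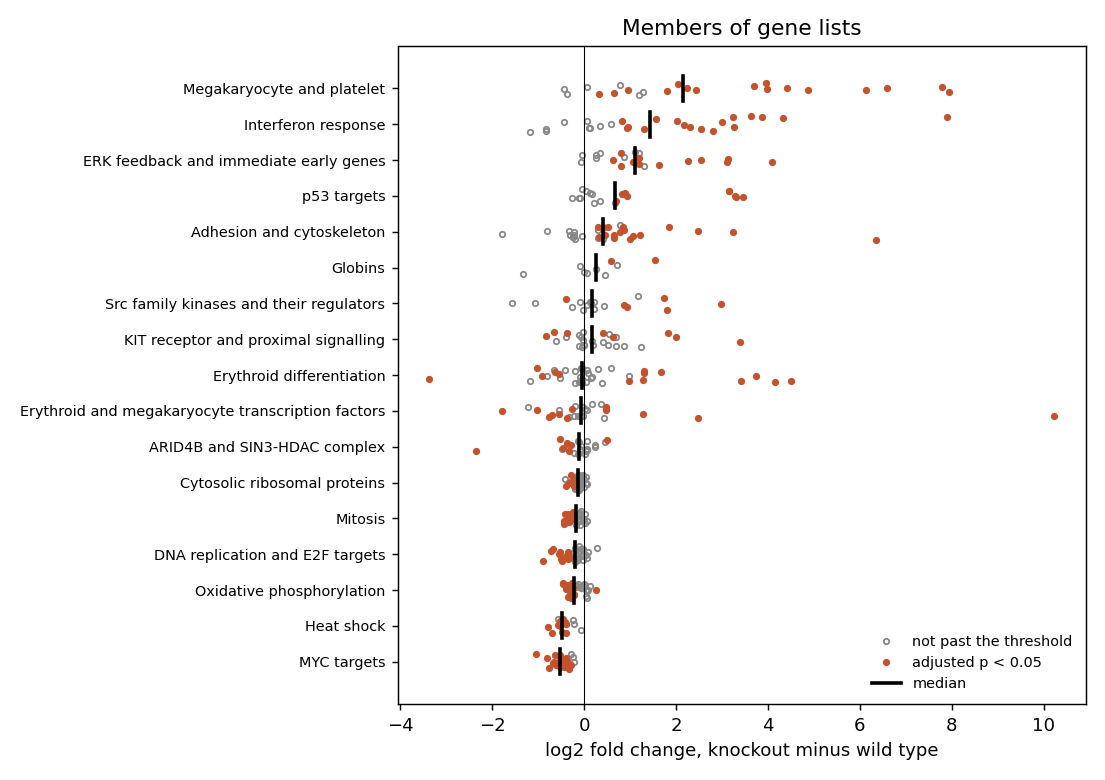
Log2 fold change of knockout over wild type for the tested members of 17 gene lists, the 7 main lists and the others past the threshold, with a point for each gene, filled where its adjusted p was under 0.05, and a line at the median. Megakaryocyte and platelet genes have a median of 2.14 and MYC targets a median of -0.52, while erythroid differentiation genes spread from AHSP at -3.37 to TRIM10 at 4.51.

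Markers of other cell types were tested to see what else the cultures expressed. The lists held 20 stem and progenitor, 19 mast cell and basophil, 30 granulocyte and monocyte, 20 lymphocyte and 20 epithelial and fibroblast genes. Most members of each did not pass the expression filter and were not tested. A member near 0 in wild type, such as FCER1A, passed it only through the knockout libraries. Stem and progenitor genes had 8 tested members, of which 2 rose and 2 fell, with the adhesion receptor CD44 up from 0.822 to 66.1 ± 52.8 CPM (6.34, adjusted p = 0.00194) and the transcription cofactor LMO2 down 1.64-fold (adjusted p = 0.0201). CD34 had 0 counts in each wild-type library and 2, 2 and 1 in the knockout libraries and was not tested. Mast cell and basophil genes rose in 3 of 6 members, with the IgE receptor chain FCER1A at a ratio of summed counts of 67.8 (95% interval 22.9 to 332). Of granulocyte and monocyte genes 1 of 9 rose, CD68 by 1.92-fold (adjusted p = 0.0448), and 0 rose when adjusted over the list alone. CD68 missed the threshold when any wild-type library (0.127 to 0.135) or knockout replicate 1 or 3 (0.0831 and 0.107) was left out and with limma-voom (0.0823), and LMO2 when any wild-type library was left out (0.0579 to 0.08). Of 5 lymphocyte genes 1 rose and 1 fell (2 and 1 adjusted over the list alone), the latter LEF1, a mediator of Wnt signals (-0.96, adjusted p = 0.00874). Of 7 epithelial and fibroblast genes 5 rose and 1 fell. The collagen gene COL1A1 rose from 0.522 to 20.9 ± 11.9 CPM (5.33, adjusted p = 0.00329), and the epithelial adhesion gene EPCAM fell from 81.7 ± 1.95 to 20.4 ± 7.89 CPM (4.01-fold, adjusted p = 0.00292). For the stem cell, mast cell and epithelial lists the counts adjusted over the list alone were the same. With camera none of these 5 lists passed (adjusted p = 0.898, 0.462, 0.514, 0.684 and 0.244 in the order given), but the epithelial and fibroblast list did without knockout replicate 1 (0.0123), and the mast cell and basophil list passed with fry (0.0435). When any wild-type library was left out 1 of the 7 epithelial and fibroblast genes rose, and with limma-voom 2. Leaving out wild-type replicate 1, 2 or 3 gave 1 rise each time and 1, 0 and 0 falls of stem and progenitor genes, 2 rises each time of mast cell and basophil genes, and 0, 0 and 1 rises of lymphocyte genes. Camera pointed down for the stem cell list, whose mean was 0.58 and whose median was 0.01 (-0.12 without knockout replicate 2).

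MYC targets fell in 26 of 29 members, also adjusted over the list alone, and rose in 0, with a median of -0.52. The spermidine synthase SRM fell from 374 ± 9.18 to 182 ± 24.5 CPM (-1.04, SE 0.10, adjusted p = 0.00146), in a block of chromosome 1 with medians of -0.49, -0.47 and -0.11, which TNFRSF8 shares. This was the only list past the threshold with both correlations (camera adjusted p = 3.21e-11, and adjusted p = 0.0397 with an estimated correlation). Heat shock genes fell in 11 of 16 members (14 adjusted over the list alone), the mitochondrial chaperonin HSPE1 by 0.79 on the log2 scale (adjusted p = 0.00133). DNA replication and E2F targets fell in 12 of 35, UHRF1, a reader of hemimethylated DNA, by 0.90 (adjusted p = 0.00135), and mitosis genes in 11 of 29, the cyclin CCNA2 by 0.44 (adjusted p = 0.00365), with the same counts adjusted over each list alone. Without knockout replicate 1 there were also 2 rises among replication genes. Oxidative phosphorylation genes fell in 14 of 33 and rose in 1 (17 and 1 adjusted over the list alone), the ATP synthase subunit ATP5F1 by 0.46 and the cytochrome oxidase subunit COX6C up by 0.25 on the log2 scale (adjusted p = 0.0238 and 0.0311). Cytosolic ribosomal proteins fell in 6 of 40, but in 0 adjusted over the list alone, RPS2 by 0.40 (adjusted p = 0.0164). Camera gave adjusted p of 1.4e-05 for heat shock, 0.000113 for replication, 0.00111 for mitosis, 0.00252 for oxidative phosphorylation and 0.00412 for ribosomal proteins. With an estimated correlation these became adjusted p of 0.314, 0.45, 0.454, 0.645 and 0.688, and the ribosomal list also failed with fry (0.0967). Falls of this size leaned on the scaling, since with library totals alone 3 mitosis, 5 oxidative phosphorylation and 0 ribosomal protein genes fell, the ribosomal list missed the threshold (0.0634), and RPS2 (0.0557) and ATP5F1 (0.0521) lost their calls. The authors' deposited log2 fold changes were 0.21 higher at the median of shared genes. List medians here were about that size or smaller, at -0.21 for replication, -0.17 for mitosis, -0.22 for oxidative phosphorylation and -0.14 for ribosomal proteins. Without wild-type replicate 1, 2 or 3 the falls numbered 5, 3 and 3 for mitosis, 5, 4 and 4 for oxidative phosphorylation, and 0, 0 and 1 for ribosomal proteins. RPS2 and ATP5F1, the latter in a block with medians of -0.44, -0.21 and -0.11, also lost their calls with the neighbourhood offset (0.16 and 0.103), and COX6C with the spread by genotype (0.0771). Leaving out any wild-type library also ended the calls of ATP5F1 (0.0755 to 0.0835) and COX6C (0.0859 to 0.138), leaving out wild-type replicate 1 or 2 that of RPS2 (0.0609 and 0.0544), and leaving out knockout replicate 3 that of COX6C (0.058), which no expression filter ended too (0.102).

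CDKN1A, the cell cycle inhibitor p21, rose from 5.51 ± 0.939 to 54.0 ± 7.25 CPM in a narrow range of 47.1 to 61.6 CPM (3.29, SE 0.17, adjusted p = 0.000237). E2F5 fell 2.03-fold (adjusted p = 0.00519), and in the list of CDK inhibitors and RB family genes 2 of 14 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.514, down, with a mean of 0.12 and a median of -0.09 that was -0.03 without knockout replicate 3). Leaving out wild-type replicate 1, 2 or 3 left 1 rise each time and 4, 3 and 4 falls. BTG2, an antiproliferative gene, rose from 23.1 ± 2.30 to 253 ± 98.5 CPM (3.45, SE 0.28, adjusted p = 0.000865) and with it 9 of 19 tested p53 targets (9 adjusted over the list alone, beside 1 that then fell), while 0 fell over all genes tested. Of these targets 5, 5 and 6 rose without wild-type replicate 1, 2 or 3, and 1 fell without knockout replicate 1. The p53 list passed (camera adjusted p = 0.00412, and adjusted p = 0.314 with an estimated correlation). K562 cells are known to lack functional p53.

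Interferon response genes rose in 17 of 26 tested members and fell in 0 (17 and 1 adjusted over the list alone), with a median of 1.43. That list held 37 genes before the expression filter. MX2, an antiviral GTPase, reached 34.8 CPM in knockout replicate 1 but 3.21 and 1.93 in replicates 2 and 3, from 0.0508 in wild type (7.90, adjusted p = 0.0106). MX2 missed the threshold with limma-voom (0.115) and when any wild-type library was left out (0.0539 to 0.056). Adhesion and cytoskeleton genes rose in 17 of 32 members, also adjusted over the list alone, and fell in 0, with CD44 the member that rose most. Without wild-type replicate 1, 2 or 3 the rises numbered 7, 8 and 8 for interferon genes and 10, 10 and 9 for adhesion genes. With limma-voom 11 interferon genes rose and 1 fell. Leaving out knockout replicate 1, 2 or 3 gave 1, 2 and 1 falls among interferon genes and 3, 2 and 1 among adhesion genes. Camera gave adjusted p of 0.000399 and 0.0116 for these lists, and with an estimated correlation adjusted p of 0.434 and 0.431.

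The remaining lists did not pass. Imprinted genes rose in 5 of 20 members and fell in 2 (1 without wild-type replicate 2 or 3, 3 without knockout replicate 1 or 3), with ZDBF2, normally expressed from the paternal copy, up from 0.0706 to 4.64 ± 2.48 CPM (adjusted p = 0.00305). Cancer-testis and germline genes rose in 5 of 18 and fell in 1, the transketolase-like gene TKTL1 reaching 1.66 ± 1.18 CPM (adjusted p = 0.0123, lost without wild-type replicate 1 or 2 at 0.0604 and 0.0638), and the median was 0.38 also with the member that had a genotype at 0 set to its bound, but 0.20 and 0.57 without knockout replicate 1 or 2. This list had 2 falls when any knockout library was left out. ATF4 and unfolded protein response genes rose in 3 of 27 and fell in 2, the stress factor DDIT3 with a log2 fold change of 1.26 (adjusted p = 0.00113) and the chaperone HSPA5 down 1.40-fold (adjusted p = 0.0073). Glycolysis and hypoxia genes rose in 4 of 28 and fell in 8 (5 and 8 adjusted over the list alone). NDRG1, a differentiation and hypoxia gene, rose from 1.55 to 48.5 ± 17.9 CPM (4.97, adjusted p = 0.000572) and hexokinase HK2 fell 1.87-fold (adjusted p = 0.00619). Cholesterol synthesis genes rose in 2 of 24 (1 adjusted over the list alone), SQLE by 1.67-fold (adjusted p = 0.00271), and replication-dependent histone genes in 3 of 14 (2 adjusted over the list alone), HIST2H2BE by 2.14-fold (adjusted p = 0.00149). Without wild-type replicate 1, 2 or 3 the rises numbered 3, 2 and 2 for imprinted genes, 3, 3 and 4 for cancer-testis genes, 1, 1 and 1 for cholesterol genes and 2, 2 and 1 for histone genes. ATF4 genes had 6 rises and 2 falls without knockout replicate 2, and 4 rises and 5 falls with a median of -0.15 without knockout replicate 3. Glycolysis genes had 7 rises and 8 falls without knockout replicate 1, and 6 and 8 without knockout replicate 2. Leaving out knockout replicate 1, 2 or 3 gave 3, 1 and 1 rises and 2, 1 and 3 falls of cholesterol genes, and 5, 3 and 2 rises of histone genes. With limma-voom 3 imprinted genes rose. For the imprinted, cancer-testis and ATF4 lists the counts adjusted over the list alone were the same. Camera gave adjusted p of 0.597, 0.514, 0.975, 0.789, 0.976 and 0.898 for these 6 lists in the order given. It pointed down for ATF4 genes (median 0.08, mean 0.14) and glycolysis genes (mean 0.25, and a median of 0.10 that was 0 and 0.01 without knockout replicate 1 or 3), and for cholesterol genes (mean -0.04, and a median of 0.03 that was 0.18 and -0.09 without knockout replicate 1 or 3).

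Levels along the chromosomes separated the knockout libraries from one another. In 560 genes of the short arm of chromosome 1 the median was -0.45 and -0.40 (log2) relative to wild type in knockout replicates 1 and 2 and -0.11 in replicate 3. On the long arm of chromosome 1, between 145592605 and 213446808, it was 0.31 in replicate 2 and -0.04 and -0.02 in replicates 1 and 3. On the long arm of chromosome 19, from 33463148 to 59110852, it was 0.24 in replicate 2, -0.28 in replicate 3 and 0.02 in replicate 1. Single blocks departed further, with medians of -0.94, -0.55 and -0.62 in replicate 1 for 3 neighbouring blocks of chromosome X (2746863 to 52546197), and of -0.69 and -0.70 in replicate 2 for 2 blocks of chromosome 3 (140660662 to 183402304). Compared with the other libraries of its genotype, each knockout library had 25, 27 or 35 of 238 blocks with a median beyond 0.2, and each wild-type library had 0.

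**Figure D4:**
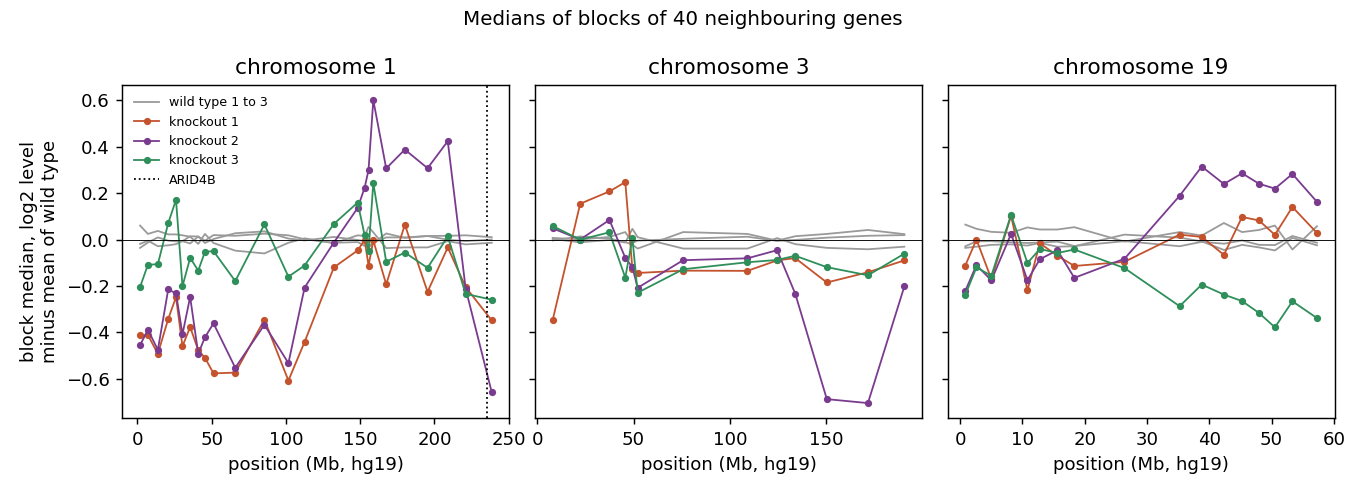
Median log2 level of blocks of neighbouring genes relative to the wild-type mean, along chromosomes 1, 3 and 19 (position in Mb on hg19), with grey lines for the 3 wild-type libraries and a coloured line for each knockout library. Knockout replicates 1 and 2 lie near -0.45 and -0.40 over the short arm of chromosome 1, and replicates 2 and 3 part in opposite directions on the long arm of chromosome 19.

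The authors' deposited table lists 3153 genes, 2787 higher and 366 lower in the knockout, and 1023 of them with an adjusted p under 0.05. Of those 1023 genes in the authors' deposited table, 999 were tested here and 996 passed the threshold with the same sign. Across the 2368 genes in both tables, all of which had the same sign, the log2 fold changes of the authors' deposited table and of edgeR correlated with Pearson r = 0.982 and Spearman rho = 0.997, which describes genes within the same libraries and not independent replicates. For the 1274 genes with at least 5 CPM on average r was 0.987 and rho 0.999. The authors' deposited table holds only genes with an unadjusted p up to 0.05 and larger changes, from these same libraries. A shared sign was therefore nearly certain beforehand, and leaving out small changes raises the correlations. The median difference was 0.21 (log2), the authors' deposited table being higher. Of the 2107 falls called here 196 were in the authors' deposited table, which holds no change smaller than 0.59. KIT had a log2 fold change of 3.25 and an adjusted p of 0.0976 in the authors' deposited table, ARID4B -2.10 and 0.0354, and ITGA2B 4.01 and 0.0376.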

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

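The fit with a spread of its own for each genotype and the offset for neighbouring genes were chosen after seeing the data, and all other alternatives before. ARID4B stayed lower and past the threshold under every alternative run, with log2 fold changes from -1.94 with the neighbourhood offset to -2.43 without knockout replicate 1. The number of genes past the threshold (4619) lay between 4178 and 5630 under the alternatives that keep all 6 libraries and do not use the replicate block, and the number changed at least 2-fold (1710) between 1350 and 2231. Leaving out a library gave 2097 to 5456 genes and 940 to 2154 at least 2-fold. The low ends came from leaving out a wild-type library (2349, 2097 and 2178 genes, 1011, 940 and 1003 at least 2-fold). Fewer samples alone as the cause is argued against, since leaving out knockout replicate 1, 2 or 3 gave 5456, 4853 and 5437 genes. The edgeR test fits 1 spread per gene for both genotypes, and the common dispersion was 0.105 in knockout and 0.0023 in wild type. Leaving out a wild-type library gives the knockout spread more weight in that fit, so the drop marks no wild-type library as unusual. How much of the drop this makes was not tested. Of the 11 gene lists past the threshold, 1 passed with an estimated correlation, MYC targets, and the cause was not tested. Between 10 and 14 lists passed under the other alternatives, and leaving out a library gave 11 to 12. The correlation with the authors' deposited table was 0.982 over all shared genes and 0.987 at 5 CPM or more.

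The replicate numbers did not pair the libraries, since the deviations of same-numbered libraries from their group means correlated at 0.012, 0.018 and 0.01. With the replicate number as a block 3449 genes passed, 1425 at least 2-fold, and 11 lists, and 8 of 73 named genes besides ARID4B fell below the threshold. ARID4B then had a log2 fold change of -2.36.

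No named gene past the threshold in either fit turned its direction under any alternative. Calls of named genes besides ARID4B were lost for 4 genes and gained for 1 with library totals alone, and lost for 2 and gained for 1 with upper quartile factors. With DESeq2 1 was gained and 0 lost, and with the spread by genotype 1 was lost and 2 were gained. With limma-voom 9 were lost, with no expression filter 3, and with the neighbourhood offset 4, 1 being gained. Without wild-type replicate 1, 2 or 3, 22, 24 and 21 were lost. Depth limits mainly the genes near 0 counts in wild type, whose folds are bounds or wide intervals. The simulation recovered 16% of genes changed 1.5-fold. Far fewer genes were changed there than were called in the data, so the same adjusted p asked for a smaller unadjusted p. That share therefore does not carry over, and how many small changes were missed in the data was not tested.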

Other observations

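The 29 gene families looked at were chosen after values were seen, so set tests on them are no independent evidence, and with an estimated correlation none passed (lowest adjusted p = 0.174). Only some are described here. The tests of scaling, of chromosomal blocks beyond shuffled gene order and of the ABCB1 neighbourhood were also chosen after the result was seen. Of 76 mitochondrial ribosomal protein genes, 38 fell and 0 rose (median log2 fold change -0.32), and without wild-type replicate 1, 2 or 3 the falls numbered 28, 26 and 24. Of 11 SR splicing factors, which guide exon choice, 9 fell and 0 rose (median -0.56), and of 22 hnRNP genes 14 fell and 0 rose (median -0.42). Falls also passed for 13 of 20 nucleoporins (8 without wild-type replicate 2 or 3), 11 of 20 importins and exportins (7 with library totals alone) and 10 of 27 RNA polymerase subunits, with 0 rises in each. Medians of these families stayed below 0 under the 3 other scalings. Those scalings moved the median of all genes by 0.11 (log2) at most, while the authors' deposited fold changes were 0.21 higher at the median. A shift of that size over all genes would bring RNA polymerase subunits (median -0.24) near 0. Proteasome subunits fell in 16 of 37 and rose in 2. With library totals alone 5 fell, and when any wild-type library was left out 6.

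Collagen genes rose in 9 of 16 tested members with a median of 2.14, laminins and integrins in 11 of 22, interleukin receptors in 10 of 23, and HLA class I and II genes in 4 of 5, with 0 falls in each and medians above 0 under every scaling run. These counts were lower when a wild-type library was left out. Whichever it was, 2 collagens and 1 HLA gene then rose. Without wild-type replicate 1, 2 or 3 the rises numbered 6, 7 and 6 for laminins and integrins and 4, 4 and 5 for interleukin receptors. With limma-voom 2 collagens rose. Of 8 TNF receptors 4 rose and 2 fell, but 1 rose and 0 fell when any wild-type library was left out, and of 7 ephrins and ephrin receptors 1 rose and 1 fell, with 0 falls when a wild-type library was left out.

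Among changes of at least 2-fold 1563 genes rose and 147 fell. Rises made up at least 91.4% under the 3 other scalings, so the choice among these scalings does not make the pattern. They moved the median of all genes by 0.11 (log2) at most, too little to overturn it. A larger error shared by all of these scalings was therefore not tested. A count floor that hides falls of weakly expressed genes would leave the sides even among genes that reach 10 CPM in their higher group, and there 499 rose and 84 fell (85.6%). Low wild-type levels that leave room only to rise stay open for part of the pattern. Among 8707 genes with a wild-type mean of at least 10 CPM 167 rose and 84 fell, a share of 66.5% (95% exact interval 60.3 to 72.3) between the 60% and 70% set beforehand. The interval reaches above 70%. It takes genes of the same libraries as independent, so it is too narrow and does not measure the spread between libraries. Loss of a corepressor subunit may release silent genes, a hypothesis that these libraries cannot set apart from differences between edited lines.

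Knockout libraries differed among themselves far more than wild-type libraries. Their lower depth is argued against by genes at 100 CPM or more, where the dispersion was still 17.3 times that of wild type. Copy number of chromosome segments may account for a part, since each knockout library had 25 or more blocks of neighbouring genes beyond 0.2 (log2) from the others against at most 1 in 100 shuffles of the gene order. It does not account for the whole, because with block medians removed the biological coefficient of variation was 31.4% against 32.3%. These blocks argue against the knockout libraries being repeats of the same RNA, while each wild-type library had 0 such blocks. The 3 libraries per genotype may therefore stand for different kinds of replicate. DNA was not measured, and whether the knockout libraries come from separate clones, which may differ in more than ARID4B, stays open.

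ABCB1 (chromosome 7, 87133179 to 87342639 on hg19), singled out after its values were seen, encodes the drug efflux pump P-glycoprotein. It rose from 0.840 ± 0.221 to 153 ± 8.83 CPM (n = 3), 183-fold, with knockout libraries at 150, 146 and 163 CPM (edgeR adjusted p = 1.08e-05). Amplification of its neighbourhood on both sides would raise the genes around it, but those within 1 Mb and at 5 CPM or more in wild type had a median log2 fold change of -0.09. At lower coordinates KIAA1324L, DMTF1 and CROT stood at 1.18, 0.26 and 0.35. At higher coordinates SLC25A40, DBF4 and SRI stood at -0.45, -0.60 and -0.44. These values argue against a gain of both sides, but cannot exclude a gain of 1 side or of ABCB1 alone. Drug selection while the knockout lines were made may also raise this gene, and like an effect of ARID4B it cannot be tested here, because the sources used here do not describe that step.

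For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 4619 genes and 1710 at least 2-fold, and the highest of the other splits gave 0 of each by the edgeR test (125 to 250 genes at an unadjusted p under 0.05, against 6232). Each other split mixes the genotypes in both groups, so their difference counts as spread and few calls must follow. No conclusion is drawn from that contrast. The real split gave 11 gene lists, and the highest of the other splits gave 12, with 5 of the 10 splits, the real one included, giving as many.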
